A study of Homo sapiens with 12 samples.

How the data were processed

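Expression was measured on one-colour NimbleGen human arrays, per the labels' protocols, in MCF7-tet-on-CARM1 clone 13, a derivative of the MCF-7 breast cancer line in which doxycycline (Dox) switches on a CARM1 transgene. The 12 arrays fall into 4 groups of 3, with replicates named a, b and c in each: vehicle (DMSO), Dox, oestradiol (E2) and both (Dox+E2). Per the labels, cells were grown in 10% serum and moved for 2 days to phenol red-free medium with 5% charcoal-stripped serum before E2 at 10 nM. Dox was given at 1 ug/ml for 4 days according to the treatment protocol, while the series text gives 5 days of Dox for the Dox+E2 group, and that text gives the 4 hours of E2 for this group only. One label of the Dox+E2 arrays names the second agent D2, while their titles and descriptions name E2, and they were taken as E2. The series text calls the replicates biological, and nothing used here says that they were separate cultures, so the p-values measure the spread between these samples, which may in part be technical.

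The authors deposited one file of intensity values per array, in which, per the file headers and columns, each of 47633 transcripts has the mean perfect-match signal of its probes. Of these transcripts, 47618 have 8 probes and 15 have fewer, and the annotation is that of build hg18 (NCBI Build 36). The mismatch mean is 0 throughout and the difference column equals the perfect-match mean, so no background subtraction is recorded, and the software that made the means is not given in the sources used here. The authors also deposited a table of intensity values for the whole series on a linear scale, and RMA is named in the submitters' processing notes without a version or settings. The r of the log2 values between an array of the per-array files and its own column of that table ran from 0.947 to 0.970. In deviations from each transcript's mean over the arrays, each array correlated best with its own column (12 of 12). That r ran from 0.470 for Dox+E2 c to 0.812 for Dox+E2 b, so differences between arrays matched less closely than levels. The medians of the table's columns were 296, 307 and 314 for DMSO a, b and c, 312, 293 and 278 for Dox a, b and c, 301, 321 and 307 for E2 a, b and c, and 348, 308 and 311 for Dox+E2 a, b and c. Its steps of background correction and centring stay unknown. No transcript carries a detection call, and dim transcripts were taken as those below the 40th percentile of the mean over the 12 arrays.

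The intensity values were converted to log2 and quantile-normalized between arrays. No pair of replicates of a group held the same values throughout, and r of the log2 values between replicates lay between 0.973 and 0.996. Pairs from different groups were not compared in this way. Gene names came from the arrays' own annotation, which names 45520 of the 47633 transcripts, and 41338 of these were matched through Entrez numbers to current symbols, which changed 11751 of them. The rest kept the name in the file. The transcripts cover 23685 symbols, of which 12695 have several transcripts, and the transcript with the highest mean over the 12 arrays then stood for the gene. No gene had 2 transcripts past the threshold in opposite directions.

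Each comparison was a contrast in a linear model with 1 coefficient per group over all 12 arrays (limma lmFit and eBayes, 8 residual degrees of freedom), with Benjamini-Hochberg adjustment over the 47633 transcripts and a threshold of 0.05. The comparisons were E2 against DMSO, Dox against DMSO, Dox+E2 against Dox, Dox+E2 against E2, and the interaction, which is the E2 difference with Dox minus the E2 difference without it. CARM1 was also tested by an exact two-sided permutation of its values over the 12 arrays. Between 3 and 3 arrays an exact permutation test of 1 gene cannot go below p = 0.1, so single genes rest on limma's pooled spread. The number of arrays limits the precision, with a median 95% half-width of the log2 difference of 0.29 for pairwise comparisons and 0.41 for the interaction.

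The genes named were set by a rule before the data were examined. For each pairwise comparison it takes the 8 largest increases and 8 largest decreases that passed the threshold without overlap between replicates, or, where none passed, the 3 highest and 3 lowest moderated t. For the interaction up to 5 in each direction were allowed. It adds up to 4 members of each gene list by moderated t, and CARM1, ESR1, PGR, GREB1, TFF1, CDKN1A, CDKN1B, CCNG2, GATA3, MAZ, E2F1, CCNE1 and CCND1. The 17 gene lists were also fixed beforehand: early oestradiol-induced, oestradiol-repressed, DNA replication and E2F targets, mitosis, growth arrest and p53 targets, luminal differentiation, basal and mesenchymal, interferon-stimulated, ATF4 and integrated stress response, glycolysis and hypoxia, mitochondrial respiratory chain, sterol synthesis, ribosome biogenesis, immediate early, arginine methyltransferases and receptor cofactors, markers of other cell types, and housekeeping genes. They were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over all 85 list tests (over the 17 lists for each effect averaged over the other agent), and again with camera at an estimated correlation and with fry. fry asks whether the members of a list move on balance in 1 direction, or in either direction in its mixed form, without setting them against other genes. Of the 85 tests, camera passed 9 at the preset correlation and 4 with an estimated correlation, all 4 among the 9, and fry passed 8 in its directional and 13 in its mixed form.

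The replicate letters were checked for pairing from the correlation of deviations from the group means. For E2 against DMSO all 3 same-letter pairs were above 0.1 (0.730, 0.291 and 0.292), and so were those for Dox+E2 against E2 (0.225, 0.358 and 0.147), so for these 2 comparisons a fit with the letter as a block is given beside the results it moved. The labels do not name batches, and 2 divisions in them were treated as possible batches without knowing whether they reflect processing: sample identifiers of 2 series, one holding the 4 arrays of replicate a and the other the 8 of replicates b and c, and 2 ranges of array number, the higher holding E2 b, Dox+E2 b and Dox a. Each was used as a covariate and by subsets. On the first principal component, which held 31.7% of the variance, the replicate a arrays lay between -58.1 and -26.9 and the others between 8.33 and 26.6.

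The alternatives were the letter block, either of these divisions as covariate, the series table, a second quantile normalization, median centring, an offset of 32 before log2, bright transcripts only, transcripts of a gene averaged, an intensity trend with robust moderation, array weights, the 2 compared groups alone, a threshold of 1.5-fold added to the adjusted p, unadjusted p, no moderation, and each array left out. Chosen after seeing the data were normexp background correction with an offset of 50, cyclic loess, replicates b and c alone, the low array numbers alone, the removal of both Dox-treated a arrays, and Dox and E2 effects averaged over the other agent.

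The procedure was tested on simulated data of 47633 transcripts with 200 changed. The simulated arrays were independent and had the spread of the fit without a block. They lack the structure by replicate letter, so the rates below may not hold for these arrays. At a log2 change of 1 it recovered 78.8% for E2 against DMSO, 81.7% for Dox against DMSO, 81.8% for Dox+E2 against Dox, 75.4% for Dox+E2 against E2 and 52.4% for the interaction, and at 0.5 it recovered 23.8%, 13.7%, 18.1%, 11.1% and 1.49%. None was called in the wrong direction. Software was Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9) and R 4.3.3 (limma 3.58.1).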

Results

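Transcript levels were measured on 12 one-colour arrays of MCF7-tet-on-CARM1 clone 13, an oestrogen-responsive MCF-7 breast cancer line that carries a doxycycline-inducible transgene for CARM1. CARM1 is an arginine methyltransferase that acts as a coactivator of the oestrogen receptor. The 4 groups (DMSO, Dox, E2 and Dox+E2) had 3 arrays each and made a factorial design of CARM1 induction by Dox and stimulation by oestradiol (E2, 10 nM). The array medians were 632 to 837 intensity units, with a ratio of the 95th to the 5th percentile from 34.8 on Dox+E2 a to 130 on Dox+E2 c. The differences below are log2 differences of quantile-normalized intensities with their standard errors (SE, n = 3 arrays per group) and limma's adjusted p.

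CARM1 (chromosome 19, 10843252 to 10894448 on build hg18) was measured first, since Dox is meant to raise it. Its level was 14.3 ± 0.588 (mean log2 intensity ± SD, n = 6) on the Dox-treated arrays and 13.2 ± 0.137 (SD, n = 6) on the others, a difference of 1.11 or 2.16-fold. The lowest Dox-treated array, at 13.8, lay above the highest untreated array, at 13.5, and the exact two-sided permutation p was 0.00216, the smallest that 924 regroupings allow. The rise was larger in replicate a, at 3.45-fold for Dox over DMSO and 3.62-fold for Dox+E2 over E2, than in replicate b (2.15-fold and 1.53-fold) or replicate c (1.82-fold and 1.35-fold). CARM1 did not pass in the fit over all transcripts, where it differed by 1.25 ± 0.34 for Dox against DMSO and by 0.97 ± 0.34 for Dox+E2 against E2 (limma's adjusted p = 1 in both). Nor was it among the 3 transcripts that passed for Dox against DMSO without both Dox-treated a arrays. Whether the spread between replicates kept it from passing was not tested. ESR1, which encodes the oestrogen receptor alpha, differed by -0.04 ± 0.25 for Dox against DMSO (limma's adjusted p = 1). Which part of CARM1 the probes cover, and whether they see the transgene and the native gene alike, is not given in the sources used here.

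**Figure D1:**
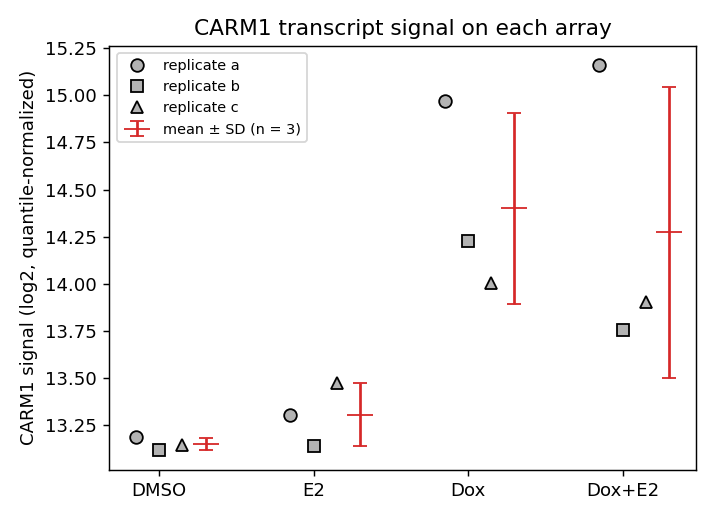
CARM1 level on each of the 12 arrays (vertical axis, log2 quantile-normalized intensity) by group (horizontal axis), with replicates a, b and c as circles, squares and triangles and the group mean ± SD (n = 3) as a red cross with bars. All 6 Dox-treated arrays lie above the 6 others, and the replicate a arrays are the highest in the Dox and Dox+E2 groups.

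E2 against DMSO asked which genes respond to oestradiol while the transgene is off. Oestradiol raised GREB1, a growth regulator whose promoter the oestrogen receptor binds (chromosome 2, 11600301 to 11649723), 6.64-fold, from 9.19 ± 0.289 to 11.9 ± 0.484 (mean log2 intensity ± SD, n = 3), a log2 difference of 2.73 ± 0.28. The largest increase was that of IL20, a cytokine of the interleukin-10 family (chromosome 1, 205105795 to 205108578), at 9.45-fold or 3.24 ± 0.38. PTGES, the terminal synthase of prostaglandin E2, rose by 2.68 ± 0.12, and CXCL12, a chemokine gene, by 2.47 ± 0.12. The gene for its receptor, CXCR4, had the largest decrease, at -0.86 ± 0.15. OLFML3 (2.58 ± 0.24), RBM24 (2.50 ± 0.17), RHOBTB1 (2.12 ± 0.21) and the neuropeptide Y receptor gene NPY1R (2.11 ± 0.20) complete the 8 largest increases, with limma's adjusted p from 5.32e-06 to 0.00337 over the 8. The remaining largest decreases were smaller, at -0.82 for RAB27B, a GTPase of secretory vesicles, -0.80 for the serine protease gene TMPRSS2, -0.73 for PPP1R3C, -0.72 for PPFIBP2, -0.71 for the adhesion gene AMIGO2, -0.70 for FUT8-AS1 and -0.65 for RASD1, with limma's adjusted p from 0.00531 to 0.0318 including CXCR4.

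In all, 260 transcripts passed limma's threshold for E2 against DMSO, 238 higher and 22 lower, and 121 of the higher and 0 of the lower ones differed by at least 2-fold. Counted once per gene, by its transcript with the highest mean, 121 genes rose and 15 fell, and 30 further genes passed only in another transcript. All 260 transcripts had replicate values that did not overlap between the groups. This held for 14.4% of all transcripts, where chance gives 10% for independent arrays. At an unadjusted p under 0.05 there were 2746.

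Among the 48 early oestradiol-induced genes, 14 rose, or 27 with the replicate letter as a block, and 38 when adjusted over the list alone. All 48 lay above 0, with a median of 0.89. The kinase gene SGK3 rose by 1.65 ± 0.12, the Ras-related growth inhibitor gene RERG by 1.43 ± 0.12 and the ubiquitin ligase gene SIAH2 by 1.11 ± 0.09. The classical targets TFF1 and CCND1 were at 1.85 ± 0.40 (limma's adjusted p = 0.106) and 0.55 ± 0.19 (limma's adjusted p = 0.523) and did not pass without a block. With the letter as a block TFF1 passed (limma's adjusted p = 0.00384) and CCND1 did not. PGR, the progesterone receptor gene, was at 0.14 ± 0.34 (limma's adjusted p = 1). The list passed with camera at an adjusted p of 2.79e-63, and at an adjusted p of 0.0218 with an estimated correlation. The median was 0.84 in replicate a alone and 0.84 in replicates b and c alone.

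None of the 17 oestradiol-repressed genes passed on its own without a block, while with the letter as a block TP53INP1 (-0.54) and PIK3IP1 (-0.44) fell. Adjusted over the list alone, 6 fell and 1 rose, the median was -0.33, and the list passed downwards (camera adjusted p = 3.46e-06, and 0.0218 with an estimated correlation). The interleukin-1 receptor gene IL1R1 was at -0.94 ± 0.20 (limma's adjusted p = 0.0930), TGFB3 at -0.54 ± 0.12 (0.108) and the p53-induced gene TP53INP1 at -0.54 ± 0.14 (0.211). The median was -0.35 in replicate a alone and -0.34 in replicates b and c alone.

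Ribosome biogenesis genes lay higher with E2, with 26 of 27 above 0 and a median of 0.48. RRS1 (0.71 ± 0.08), POLR1B, which encodes a subunit of RNA polymerase I (0.53 ± 0.07), and the RNA helicase gene DDX21 (0.55 ± 0.10) were the 3 that rose, against 15 adjusted over the list alone. With the letter as a block NOP16 (0.83) and NOP56 (0.53) passed too. The list's camera adjusted p was 7.60e-24, and with an estimated correlation the adjusted p was 0.0969, past the threshold no longer. The median was 0.46 in replicate a alone and 0.45 in replicates b and c alone. Of the 24 immediate early genes FOS rose, by 1.71 ± 0.22, and 3 rose adjusted over the list alone. EGR3, which passed only with the letter as a block, was at 1.01 ± 0.20 (limma's adjusted p = 0.0628) and MYC at 0.82 ± 0.23 (0.274). The EGR3 transcript was dim, at signal percentile 36.6. The median of the immediate early genes was 0.06, and the camera adjusted p of 0.00427 became an adjusted p of 0.157 with an estimated correlation. Without E2 b the list no longer passed (adjusted p = 0.0681, from 0.000186 to 0.0783 over 26 alternatives). The median was -0.01 in replicate a alone, opposite in sign to the 0.05 in replicates b and c alone.

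Of the glycolysis and hypoxia genes, SLC2A1, which encodes the glucose transporter GLUT1, rose by 1.01 ± 0.10 and the hexokinase gene HK2 by 0.56 ± 0.10, the same 2 of 21 adjusted over the list alone. The list did not pass with camera (adjusted p = 0.357) and passed with fry, at an adjusted p of 0.0303. Its test and mean (0.05) pointed up, and its median (-0.000914) lay just below 0. Among 24 arginine methyltransferases and receptor cofactors NRIP1, a corepressor gene that is also on the early list, rose by 1.06 ± 0.16, with 2 adjusted over the list alone and a camera adjusted p of 0.320. CARM1 itself was at 0.16 ± 0.34 (limma's adjusted p = 1).

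None of the other 11 lists passed with camera for E2 against DMSO, and none of their members passed over all transcripts without a block. With the letter as a block CDC25A (0.83), an E2F target, and GDF15 (0.80), of the ATF4 list, rose, while BTG2 (-0.79) and TP53INP1 (-0.54) of the growth arrest list, TP63 (-0.86) of the basal list and DDIT4 (-0.41) of the ATF4 list fell. The members passing under the block alone are named after their values were seen. The medians were 0.13 for the 46 DNA replication and E2F targets (adjusted p = 0.0947), -0.07 for the 32 mitosis genes (0.968), -0.04 for the 27 growth arrest and p53 targets (0.661), -0.07 for the 27 luminal differentiation genes (0.981), -0.09 for the 20 basal and mesenchymal genes (0.560), -0.10 for the 28 interferon-stimulated genes (0.816), 0.02 for the 24 ATF4 and integrated stress response genes (0.981), -0.03 for the 32 mitochondrial respiratory chain genes (0.771), 0.02 for the 22 sterol synthesis genes (0.816), -0.06 for the 19 markers of other cell types (0.958) and -0.03 for the 14 housekeeping genes (0.981). Adjusted over the list alone, 2 growth arrest and p53 targets fell and 1 luminal gene rose, and of the ATF4 list 1 rose and 2 fell. The test of the ATF4 list pointed down with its mean (-0.00537) against a median above 0, and that of the housekeeping list up with its mean (0.02) against a median below 0. The cell cycle regulators were at 0.09 ± 0.37 for E2F1, 0.19 ± 0.14 for CCNE1, -0.25 ± 0.21 for CDKN1A, 0.03 ± 0.26 for CDKN1B and -0.53 ± 0.33 for CCNG2, and the transcription factor genes at 0.03 ± 0.07 for GATA3, 0.01 ± 0.08 for MAZ and -0.07 ± 0.25 for ESR1 (limma's adjusted p = 1 for each).

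With the replicate letter as a block the count for E2 against DMSO was 545, 467 higher and 78 lower. Under the block the DNA replication and E2F targets also passed (camera adjusted p = 1.45e-06, from 1.24e-06 to 0.903 over 26 alternatives, and adjusted p = 0.638 with an estimated correlation), and the ribosome biogenesis list passed with an estimated correlation too (adjusted p = 0.0102). Replicates b and c alone gave 781 transcripts, 609 higher and 172 lower, and the low array numbers alone gave 93, while replicate a and the high array numbers have 1 array per group at most and allow no test. The count moved by over 1.5 times without DMSO a (122), DMSO b (117), DMSO c (134), E2 b (140), E2 c (133) or Dox+E2 a (399), and the genes of the 8 largest increases passed in all 30 alternatives that test single genes by adjusted p. The number of lower transcripts varied more, with 1 under median centring, 2 without DMSO b and 8 in the series table, against 78 with the letter as a block. The 8 largest decreases therefore did not all pass in every alternative.

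Dox against DMSO asked what CARM1 induction, together with Dox itself, changes without oestradiol. No transcript passed limma's threshold, and 432 (0.907%) lay at an unadjusted p under 0.05. Replicate values did not overlap for 6.08% of transcripts, where chance gives 10%. Both shares lie below what chance gives for unchanged independent arrays, so the absence of calls is weak evidence of no change. CARM1 (1.25 ± 0.34) and ADAMTS9, which encodes a secreted metalloprotease (0.48 ± 0.13), had the highest moderated t of the named genes, with LOC643260 (0.40 ± 0.11), and ZSCAN5DP (-0.29 ± 0.08), AMBP (-0.42 ± 0.12) and NSFL1C (-0.25 ± 0.08) the lowest (limma's adjusted p = 1 for each). The oestradiol targets were at -0.04 ± 0.28 for GREB1, -0.27 ± 0.40 for TFF1, 0.42 ± 0.34 for PGR and -0.23 ± 0.19 for CCND1, and the cell cycle inhibitors at 0.12 ± 0.21 for CDKN1A, 0.19 ± 0.26 for CDKN1B and 0.10 ± 0.33 for CCNG2. GATA3 (0.09 ± 0.07), MAZ (-0.03 ± 0.08), E2F1 (-0.07 ± 0.37) and CCNE1 (-0.02 ± 0.14) did not pass either (limma's adjusted p = 1 for each).

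No list passed for Dox against DMSO with camera at either correlation in the fit without a block, and 0 members of any list passed over all transcripts or adjusted over the list alone. The mitosis genes came nearest, with a median of -0.24 and 1 of 32 above 0 (camera adjusted p = 0.0707, and 0.994 with an estimated correlation), with TPX2 at -0.27 ± 0.38 and PLK1 at -0.38 ± 0.65. The median was -0.58 in replicate a and -0.07 in replicates b and c, and without Dox a it was 0.36, past the threshold upwards (adjusted p = 0.0349, from 8.99e-17 to 0.956 over 26 alternatives). That fit kept replicate a, where mitosis genes were low, on the DMSO side only. The respiratory chain genes had a median of -0.06 (0.0788). The early oestradiol-induced genes had a median of -0.05 (0.558), the E2F targets of -0.13 (0.229), the interferon-stimulated genes of -0.20 (0.262) and the growth arrest genes of 0.08 (0.124). In this comparison the same-letter pairs a and b correlated at 0.423 and 0.406, while the replicate c pair was at -0.0668, below the 0.1 set for pairing. With the letter as a block, camera at the preset correlation passed the mitosis genes (adjusted p = 1.54e-16), the E2F targets (6.47e-07) and the interferon-stimulated genes (1.67e-06) downwards and the growth arrest genes (0.00208) upwards. With an estimated correlation under the block the adjusted p was 0.428, 0.638, 0.634 and 0.225. The E2F median was -0.41 in replicate a and 0.00239 in replicates b and c, the interferon-stimulated median -0.36 and -0.07, and the growth arrest median 0.11 and 0.04. Over 26 alternatives the lists passed in 13, 9, 9 and 6, in either direction, and the adjusted p of the last 3 ran from 3.25e-07 to 0.986, from 1.67e-06 to 0.953 and from 0.00208 to 0.722. The test and median of the arginine methyltransferase and housekeeping lists pointed down and their means (0.02 and 0.0026) up. The 95% interval of the difference lay within 2-fold for 96.3% of transcripts. Other settings gave other counts: replicates b and c alone passed 274 transcripts (272 higher, 2 lower), array weights 3422, and a test without moderation 1, ABT1 (-0.15, adjusted p = 0.0179), which was named after its value was seen. The fit with array weights leaned on DMSO b (weight 7.63) and Dox b (3.85), against 0.245 to 1.27 for the other arrays of these groups.

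Dox+E2 against Dox asked which genes respond to oestradiol once CARM1 is induced. The genes with the largest increases were largely those seen without Dox: IL20 rose by 3.01 ± 0.38, GREB1 by 2.64 ± 0.28 (6.23-fold), PTGES by 2.62 ± 0.12, OLFML3 by 2.62 ± 0.24, RBM24 by 2.52 ± 0.17, CXCL12 by 2.29 ± 0.12, RHOBTB1 by 2.21 ± 0.21 and the sialyltransferase gene ST8SIA6 by 2.13 ± 0.17 (limma's adjusted p from 8.82e-06 to 0.0055). CXCR4 again had the largest decrease, at -0.87 ± 0.15, followed by FUT8-AS1 (-0.70), RAB27B (-0.69), AMIGO2 (-0.65), TMPRSS2 (-0.65), the growth factor gene TGFB3 (-0.63), the kinase gene DYRK1B (-0.62) and the transcription factor gene GATA2 (-0.60), with limma's adjusted p from 0.00923 to 0.0429. A total of 294 transcripts passed, 279 higher and 15 lower, with 120 higher and 0 lower by at least 2-fold, and 5205 at an unadjusted p under 0.05. Once per gene, by its transcript with the highest mean, 132 rose and 10 fell, and 49 further genes passed only in another transcript. Replicate values did not overlap for any of the 294, as for 12.9% of all transcripts where chance gives 10% for independent arrays.

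The early oestradiol-induced genes again lay higher, 47 of 48 above 0 with a median of 0.80, and 14 rose, or 36 adjusted over the list alone (camera adjusted p = 2.01e-40, and 0.0487 with an estimated correlation). SGK3 rose by 1.77 ± 0.12, RERG by 1.56 ± 0.12 and SIAH2 by 1.20 ± 0.09, while TFF1 was at 2.07 ± 0.40 (limma's adjusted p = 0.0555), CCND1 at 0.80 ± 0.19 (0.122) and PGR at -0.68 ± 0.34 (0.503). Of the 17 repressed genes TGFB3 fell, and adjusted over the list alone 4 fell and 1 rose, with a median of -0.29 (camera adjusted p = 0.000628, and 0.0487 with an estimated correlation). KLF4, a transcription factor gene on that list, was at 0.58 ± 0.13 (limma's adjusted p = 0.106). Of the 27 ribosome biogenesis genes RRS1 (0.53 ± 0.08), POLR1B (0.46 ± 0.07) and DDX21 (0.57 ± 0.10) rose, with 12 adjusted over the list alone and a median of 0.43 (camera adjusted p = 8.67e-13, and adjusted p = 0.279 with an estimated correlation). Of the immediate early genes FOS (1.68 ± 0.22) and EGR3 (1.09 ± 0.20, a dim transcript) rose, with 4 adjusted over the list alone and a median of 0.15 (camera adjusted p = 0.0174, and adjusted p = 0.255 with an estimated correlation). Without Dox+E2 c the immediate early list did not pass (adjusted p = 0.0752, from 0.000399 to 0.158 over 26 alternatives).

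SLC2A1 rose by 0.91 ± 0.10 and NRIP1 by 0.92 ± 0.16, the only members of the glycolysis list and of the methyltransferase and cofactor list to pass for Dox+E2 against Dox. Adjusted over the list alone there were 1 and 4, and in lists with no member past the threshold 2 growth arrest and p53 targets fell, 1 luminal gene rose, 1 basal gene fell, and 1 ATF4 gene rose and 1 fell. HK2 was at 0.35 ± 0.10 (limma's adjusted p = 0.218), and BBC3, which encodes the p53 target PUMA, at -0.48 ± 0.10 (0.0695). No other list passed with camera, and the mitosis genes had a median of 0.04 (adjusted p = 0.883) and the E2F targets of 0.16 (0.244). The tests of the luminal and glycolysis lists pointed up with their means (0.00757 and 0.05) against medians of -0.01 and -0.02, and those of the respiratory chain list and the markers of other cell types down with their means (-0.02 and -0.01) against medians of 0.00603 and 0.00594. CDKN1A was at -0.30 ± 0.21, CDKN1B at -0.25 ± 0.26, CCNG2 at -0.61 ± 0.33, E2F1 at -0.25 ± 0.37, CCNE1 at 0.17 ± 0.14, GATA3 at -0.05 ± 0.07, MAZ at -0.03 ± 0.08, ESR1 at -0.04 ± 0.25 and CARM1 at -0.13 ± 0.34, none past the threshold.

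In replicate a alone the medians of the early induced, repressed, ribosome biogenesis and immediate early lists were 0.77, -0.35, 0.44 and 0.04, and in replicates b and c alone 0.83, -0.32, 0.33 and 0.19. Replicates b and c alone passed 3866 transcripts for Dox+E2 against Dox (1959 higher, 1907 lower) and the low array numbers alone 174. The balance of directions depended on the setting, with 108 higher and 0 lower under median centring and 3921 higher and 3730 lower with array weights. The count moved by over 1.5 times without Dox a (1404, of which 665 higher and 739 lower), DMSO b (179), Dox b (131), Dox c (103), Dox+E2 b (102) or Dox+E2 c (133).

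Dox+E2 against E2 asked what CARM1 induction changes while oestradiol is present. No transcript passed limma's threshold, and 610 (1.28%) lay at an unadjusted p under 0.05, with 0 passing without moderation and 0 with array weights. Replicate values did not overlap for 4.04% of transcripts, where chance gives 10%. The shares of 1.28% and 4.04% are again below those of chance for unchanged independent arrays, so the absence of calls is weak evidence of no change. CARM1 was at 0.97 ± 0.34. The highest moderated t belonged to MGC40069 (0.31 ± 0.08), LOC643626 (0.29 ± 0.07) and LINC01011 (0.33 ± 0.10), and the lowest to the kinase gene TNK1 (-0.30 ± 0.08), TMIE (-0.46 ± 0.13) and PREX1, which encodes a Rac exchange factor (-0.34 ± 0.10). The oestradiol targets were at -0.14 ± 0.28 for GREB1, -0.05 ± 0.40 for TFF1, -0.40 ± 0.34 for PGR and 0.02 ± 0.19 for CCND1. E2F1 was at -0.41 ± 0.37, CCNE1 at -0.04 ± 0.14, CDKN1A at 0.07 ± 0.21, CDKN1B at -0.09 ± 0.26, CCNG2 at 0.02 ± 0.33, GATA3 at 0.01 ± 0.07 and MAZ at -0.07 ± 0.08 (limma's adjusted p = 1 for each gene named).

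The ribosome biogenesis genes passed downwards for Dox+E2 against E2 (camera adjusted p = 0.00881), with 22 of 27 below 0, a median of -0.07 and 0 members past the threshold over all transcripts or adjusted over the list alone. With an estimated correlation the adjusted p was 0.994. RRP12, a factor in ribosomal RNA processing, was at -0.36 ± 0.12. The list did not pass without Dox+E2 a (adjusted p = 0.496) or without E2 c (0.694), in a range of 1.98e-06 to 0.694 over 26 alternatives. Its median was -0.09 in replicate a and -0.08 in replicates b and c. With the letter as a block 3 more lists passed downwards at the preset correlation: DNA replication and E2F targets (median -0.12, camera adjusted p = 2.42e-05), mitosis genes (-0.11, 3.22e-05) and interferon-stimulated genes (-0.17, 7.06e-06). Their adjusted p with an estimated correlation under the block was 0.652, 0.668 and 0.634. The adjusted p at the preset correlation ran over 26 alternatives from 3.85e-06 to 0.832, from 1.86e-05 to 0.943 and from 7.06e-06 to 0.959. In replicate a their medians were -0.31, -0.41 and -0.40, and in replicates b and c -0.02, 0.03 and -0.03. The early oestradiol-induced genes had a median of -0.05 (0.264). The test and median of the markers of other cell types (-0.00123) pointed down and their mean (0.03) up. The 95% interval of the difference lay within 2-fold for 96.1% of transcripts.

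The interaction tested directly whether the oestradiol response differed once CARM1 was induced. No transcript passed limma's threshold, 501 (1.05%) lay at an unadjusted p under 0.05, and 0 passed without moderation or with array weights. The share of 1.05% is below that of chance for unchanged independent arrays, so the absence of calls is weak evidence of an equal response. PGR had the largest difference among the genes fixed beforehand, at -0.82 ± 0.48, followed by E2F1 (-0.34 ± 0.52), CDKN1B (-0.29 ± 0.36), CARM1 (-0.28 ± 0.48), CCND1 (0.25 ± 0.27) and TFF1 (0.22 ± 0.57), while GREB1 was at -0.09 ± 0.40, GATA3 at -0.08 ± 0.10, CCNG2 at -0.07 ± 0.46, CDKN1A at -0.05 ± 0.29, ESR1 at 0.04 ± 0.35, MAZ at -0.04 ± 0.11 and CCNE1 at -0.02 ± 0.20 (limma's adjusted p = 1 for each). The PGR transcript lay close to the limit for dim transcripts (signal percentile 42.6). The highest moderated t belonged to LOC441582 (0.50 ± 0.14), EPCIP (0.30 ± 0.09) and LOC645194 (0.30 ± 0.09), and the lowest to LOC643260 (-0.54 ± 0.16), LOC653733 (-0.62 ± 0.18) and the integrin gene ITGAD (-0.32 ± 0.09). No list passed, with medians of -0.02 for the early oestradiol-induced genes (camera adjusted p = 0.816), 0.03 for the repressed genes (0.883), -0.05 for ribosome biogenesis (0.320) and 0.10 for mitosis (0.816). Medians and tests differed in sign for the E2F, interferon-stimulated, ATF4, glycolysis, other cell type and housekeeping lists (medians 0.02, 0.02, -0.00154, 0.00935, 0.00774 and -0.04). The means of the ATF4 (0.00861) and glycolysis (-0.00584) lists went with the test and those of the remaining 4 with the median. The 95% interval lay within 2-fold for 89.9% of transcripts, for which smaller differences in response remain possible. For the remaining transcripts differences of 2-fold or more remain possible too. The simulation recovered 52.4% of interactions at a log2 change of 1. Its independent arrays do not match these, so that rate sets no bound on what was missed here.

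Across transcripts, which are not independent replicates, the oestradiol differences without and with Dox correlated at r = 0.604, and at r = 0.973 over the 348 transcripts that passed in either. These comparisons share no array. All 348 had the same sign in both, 198 were higher in both where independent lists would share 1.39, 8 were lower in both where they would share 0.00693, and 0 went opposite ways. The median difference of the 260 transcripts that passed without Dox was 0.94 there and 0.93 with Dox. The Dox differences without and with E2 correlated at r = -0.125. For comparisons that share arrays, E2 and Dox against DMSO correlated at r = 0.0858 (covariance 0.00228) and both Dox+E2 comparisons at r = 0.396 (covariance 0.0140), where simulated unchanged groups gave r = 0.50 and a covariance of 0.0169. The simulated groups were independent and had the spread of the fit without a block, which includes the differences between replicate letters. They therefore do not match these arrays, and no conclusion is drawn from them.

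**Figure D2:**
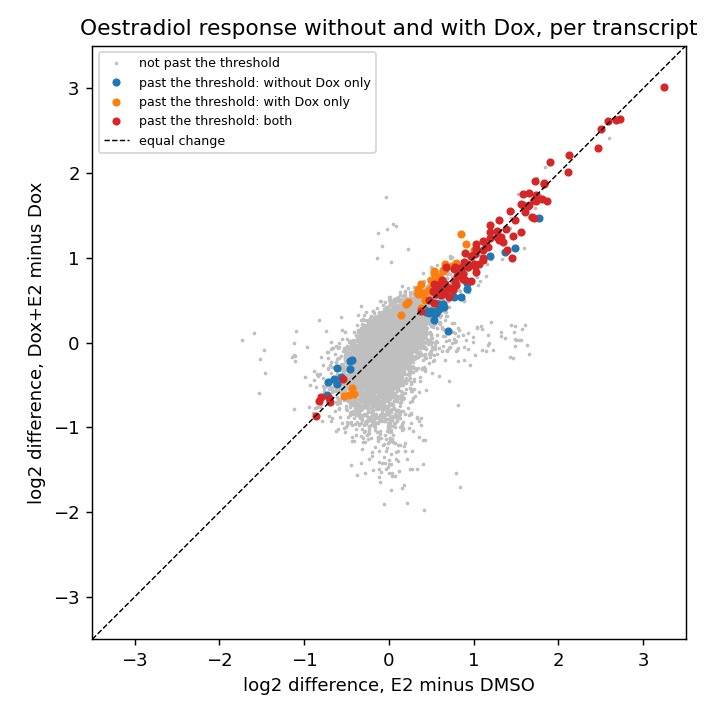
Log2 difference E2 minus DMSO (horizontal axis) against Dox+E2 minus Dox (vertical axis) for 1 transcript per gene, the one with the highest mean. Genes past limma's threshold without Dox only are in blue, with Dox only in orange and in both in red, with a dashed line of equal change. The coloured points, from 136 genes past the threshold without Dox and 142 with Dox, lie near the line. All have the same sign in both comparisons.

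The arrays differed by replicate letter in ways that the treatments do not describe. In every group the mitosis genes lay lower and the interferon-stimulated genes higher in replicate a than in replicates b and c, by -1.22 and 1.68 (mean log2 difference over the list) in DMSO, -1.18 and 1.51 in E2, -1.72 and 1.30 in Dox, and -1.60 and 1.09 in Dox+E2. The DNA replication and E2F targets lay lower by -1.04 on average and the early oestradiol-induced genes by -0.35, while the sterol synthesis genes lay higher by 0.37. Permuting the letters within groups gave an exact p of 0.0123, the smallest that 81 arrangements allow, or 0.0209 adjusted over the 17 lists, for these 5 lists and 5 others: growth arrest (-0.09), basal (-0.295), glycolysis (0.08), ribosome biogenesis (-0.19) and housekeeping (-0.08).

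**Figure D3:**
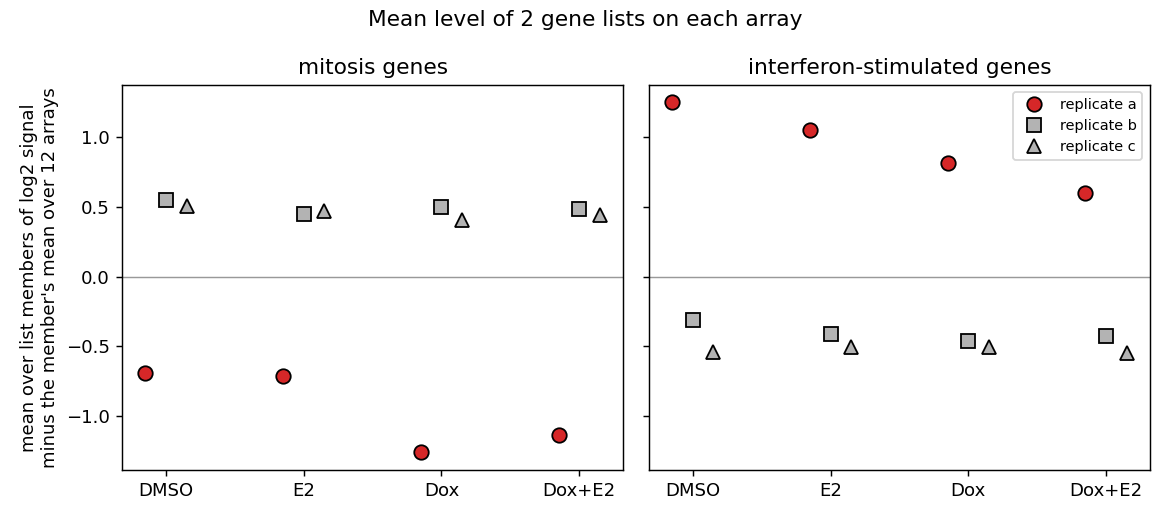
Mean level of the mitosis genes (left) and the interferon-stimulated genes (right) on each array, as the mean over list members of the log2 intensity minus that member's mean over the 12 arrays (vertical axis), by group (horizontal axis), with replicate a as red circles, b as grey squares and c as grey triangles. The 4 replicate a arrays lie below 0 for the mitosis genes and above 0 for the interferon-stimulated genes, and the other 8 arrays lie on the opposite side.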

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

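The alternatives with normexp, cyclic loess, replicates b and c alone, low array numbers alone and both Dox-treated a arrays left out were chosen after seeing the data. Of 13771 values of named genes under alternatives, 13213 kept their side of the threshold, 359 of these uncalled and with a changed sign, 313 lost the call, 245 gained one and 0 reversed while called. Of 2210 list values, 2047 kept their side, 250 of these uncalled and with a changed sign, 7 lost the call, 128 gained one and 28 reversed with a call. Of 221 counts, 162 stayed within 1.5 times. CARM1 kept its rise with Dox in all 29 alternatives run for it, from 0.75 to 1.24. The cause of the changes below was not tested, except that unadjusted p and fewer arrays change a count by construction. Leaving out a replicate a array on a single side of a contrast likewise shifts the lists that set replicate a apart.

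With the replicate letter as a block, 545 transcripts passed for E2 against DMSO, 256 of them among the 260. For Dox+E2 against Dox 593 passed, 291 among the 294. In that comparison the same-letter pairs a, b and c correlated at 0.319, 0.0456 and 0.538, so the replicate b pair fell short of the 0.1 set for pairing. With the identifier series as covariate the counts were 695 and 791, with only the 2 compared groups 166 and 66, without moderation 168 and 169, and at unadjusted p 2746 and 5205. With median centring they were 121 (120 higher, 1 lower) and 108 (108 higher, 0 lower). Array weights gave 844 (674 higher, 170 lower) and 7651 (3921 higher, 3730 lower), with weights from 0.161 for Dox+E2 a to 7.63 for DMSO b. Averaging the transcripts of a gene gave 180 for Dox+E2 against Dox. Replicates b and c alone gave 781 and 3866, the low array numbers 93 and 174, and removal of both Dox-treated a arrays 527 and 1629. Leaving out 1 array at a time gave 117 to 399 for E2 against DMSO and 102 to 1404 for Dox+E2 against Dox, where a group left with 2 arrays was fitted with the pooled spread.

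For Dox against DMSO array weights gave 3422 transcripts, no moderation 1, unadjusted p 432, replicates b and c alone 274, and removal of both Dox-treated a arrays 3, which were KIFC3 (1.05), MMP14 (1.03) and CD177 (0.94), named after their values were seen. Unadjusted p gave 610 for Dox+E2 against E2 and 501 for the interaction, and the other alternatives gave 0 for both.

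The lists that reversed were mostly those that set replicate a apart. With median centring the median of the sterol synthesis genes was -0.10 for Dox against DMSO and that of the respiratory chain genes 0.17 for Dox+E2 against Dox. Over the arrays left out in turn, the mitosis median ran from -0.51 to 0.33 for E2 against DMSO, from -0.65 to 0.36 for Dox against DMSO, from -0.56 to 0.59 for Dox+E2 against Dox, from -0.52 to 0.41 for Dox+E2 against E2 and from -0.45 to 0.65 for the interaction. The interferon-stimulated median ran from -0.61 to 0.39 for E2 against DMSO, from -0.69 to 0.30 for Dox against DMSO, from -0.42 to 0.27 for Dox+E2 against E2 and from -0.45 to 0.46 for the interaction. The median of the E2F targets ran from -0.42 to 0.29 for Dox against DMSO, from -0.43 to 0.26 for Dox+E2 against E2 and from -0.43 to 0.38 for the interaction, that of the sterol genes from -0.12 to 0.15 for Dox against DMSO, and that of the respiratory chain genes from -0.13 to 0.065 for Dox+E2 against E2. With the low array numbers alone the E2F, mitosis and sterol medians were 0.29, 0.36 and -0.12 for Dox against DMSO, the E2F and mitosis medians -0.44 and -0.84 for Dox+E2 against Dox, and the mitosis median -0.54 for the interaction. Without both Dox-treated a arrays those for Dox against DMSO were again 0.29, 0.36 and -0.12, and the E2F, mitosis and respiratory chain medians were 0.26, 0.41 and 0.065 for Dox+E2 against E2.

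The early oestradiol-induced, repressed and ribosome biogenesis lists passed at the preset correlation in 26 of 26 alternatives for both oestradiol comparisons, and the immediate early list in 24 of 26. With an estimated correlation and no block the ribosome biogenesis list lost its call (adjusted p = 0.0969 without and 0.279 with Dox), and so did the immediate early list (0.157 and 0.255). With the letter as a block and an estimated correlation the ribosome biogenesis list passed (camera adjusted p = 0.0102 without and 0.0274 with Dox). The immediate early list did not (0.634 in both). The lowest value of an array was up to 248 intensity units against medians of 632 to 837, so differences of dim transcripts were compressed to an unknown extent.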

Other observations

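The tests of signal level for the Dox transcripts, all tests of the replicate a pattern, the sorting of the interaction regroupings by replicate a, the exchange of E2 within letters, and the averages over the other agent were chosen after the result was seen.

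Averaged over Dox, oestradiol raised 863 transcripts and lowered 172. Counted once per gene, by its transcript with the highest mean, 429 rose and 87 fell. By that transcript 273 and 68 of them had not passed in either single comparison. The genes below are named after their values were seen. TFF1, the trefoil peptide gene used as a marker of oestrogen response, rose by 1.96 ± 0.285 (SE, 6 arrays each side, limma's adjusted p = 0.00462), the potassium channel gene KCNK5 by 2.50 ± 0.38 (0.00609), the cell cycle gene CCND1 by 0.67 ± 0.13 (0.0265) and MYC by 0.82 ± 0.16 (0.0264). The interleukin-1 receptor gene IL1R1 fell by 0.85 ± 0.14 (0.0103) and TP53INP1 by 0.59 ± 0.10 (0.0107), while PGR was at -0.27 ± 0.24 (0.701). Ribosome biogenesis genes rose in 11 of 27 cases, or 20 adjusted over the list alone, with a camera adjusted p, over the 17 lists of this average, of 2.21e-20 and an adjusted p of 0.0521 with an estimated correlation. The count and its balance depended on the setting: 1374 higher and 505 lower with the letter as a block, 1575 and 626 with the identifier series as covariate, 419 and 20 with median centring, 482 and 122 with the transcripts of a gene averaged, 3459 and 2935 with array weights, 406 and 27 with 1.5-fold added, 2644 and 2132 in replicates b and c alone, 431 and 135 with the low array numbers alone, and 1960 and 1506 without both Dox-treated a arrays. The count moved by over 1.5 times without DMSO a (663), DMSO b (607), DMSO c (679), E2 b (680), Dox a (1937), Dox c (650), Dox+E2 a (1696) or Dox+E2 b (655).

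Averaged over E2, limma called 0 transcripts for Dox, with 440 at an unadjusted p under 0.05, 0 without moderation and 0 with array weights. Camera at the preset correlation, adjusted here over the 17 lists alone, passed ribosome biogenesis (median -0.05, adjusted p = 0.0138), mitosis (-0.17, 0.0178), E2F targets (-0.14, 0.0178), interferon-stimulated (-0.17, 0.0178) and respiratory chain genes (-0.05, 0.0178), all downwards. With an estimated correlation the adjusted p was 0.638, 0.753, 0.753, 0.753 and 0.638. The decreases of 3 of these lists lay largely in replicate a, where the mean Dox difference without and with E2 was -0.57 and -0.42 for mitosis, -0.42 and -0.35 for E2F targets and -0.44 and -0.45 for interferon-stimulated genes. In replicate b it was -0.05 and 0.04, -0.00718 and 0.11, and -0.15 and -0.01, and in replicate c -0.105 and -0.03, 0.02 and -0.14, and 0.03 and -0.04. CARM1 also rose most in replicate a, 3.45-fold without and 3.62-fold with E2. A link with the CARM1 level and another difference of replicate a cannot be told apart here.

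In replicates b and c alone, 272 transcripts were higher with Dox than with DMSO, by a median of 0.94, while 2 were lower, SLC25A21 (-0.45) and LAD1 (-0.52), named after their values were seen. A response to Dox or CARM1 that also holds with oestradiol is argued against by their median Dox+E2 minus E2 of -0.00341 in the same replicates, with 48.2% above 0. A response that also holds in replicate a is argued against by a median there of -0.54, with 2.21% above 0. Signal range and normalization at low signal stay open: the median signal percentile was 42.2 (interval 40.7 to 43.2), the series table passed 0 transcripts with a median of 0.48 for these, normexp passed 483 and cyclic loess 123. A response confined to cells without oestradiol in replicates b and c was not tested.

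The mitosis genes lay lower by -1.43 and the interferon-stimulated genes higher by 1.39 in replicate a, in 32 of 32 and 28 of 28 members, and by -1.75 and 1.74 in the series table. A general shift at the same signal level is argued against by 10000 random lists of the same size and level, which ran from -0.281 to 0.229 and from -0.271 to 0.254, so that the lists stood at percentiles 0 and 100. Both differences were seen in 4 of 4 groups, which describes the pattern and tests no cause. An array processing batch and a difference between cultures cannot be told apart, since 0 arrays of replicates b and c carry the first identifier series.

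The splits of 3 against 3 arrays number 10, too few for a share under 0.05. The real count and the highest other were 260 and 0 for E2 against DMSO (1 split as large, the real one), 0 and 0 for Dox against DMSO (10), 294 and 1 for Dox+E2 against Dox (1), and 0 and 0 for Dox+E2 against E2 (10). Of 100 groupings, the real one and 99 drawn, 1 gave as many as the real 1035 for oestradiol averaged over Dox, the real one itself, with a highest other of 0. That is the smallest share these groupings allow, and this average was chosen after the result was seen, so chance is argued against and not excluded. Those regroupings exchanged arrays within a Dox state without regard to the letter. Exchanging E2 only between arrays of the same letter and Dox state, 1 of 32 arrangements gave as many, the real one, with a highest other of 3. For Dox averaged over E2 (0, highest other 0) and the interaction (0, highest other 2270) all 100 gave as many, which a real count of 0 fixes beforehand, so these regroupings decide nothing about chance. The regrouping with 2270 put all replicate a arrays on one side of the contrast. Of 9 such regroupings 2 gave any transcript, with 73 in the other, and the 90 that divided the replicate a arrays gave 0. Such counts point to a structure of the samples, and whether the replicate a difference made them was not tested further.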
